A study of Schmidtea mediterranea with 5 samples.

How the data were processed

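RNA from whole animals of the planarian flatworm Schmidtea mediterranea (the clonal asexual strain CIW4) was sequenced in 5 conditions. These were untreated animals kept in the dark, animals at the end of 8 days of light exposure, and light-exposed animals returned to the dark for 1, 2 or 8 days. Per the series' design text, 3 biological replicates of each condition were combined in equal amounts before sequencing, so each condition has 1 library. The spread between animals is therefore not measured, no p-value is given for any difference between conditions, and differences between libraries have no replicate check. The libraries were poly(A)-selected and read as 50-base single-end reads per the labels' protocols and the series' design text. The treatment text attached to the samples describes RNA interference and amputation, a different experiment from the one in the sample titles. It was not used, and groups were taken from the titles. Per the labels' growth protocol all animals were starved for 1 week before collection.

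Per the series' design text, 15 bases were trimmed from the 3' end and reads were aligned with bowtie2 to an assembled transcriptome whose contigs carry SmedASXL numbers. Per the submitters' processing notes, bcl2fastq 1.8.3 and Bowtie2 2.2.4 were used. How reads matching several contigs were counted, and whether strand was used, is not given in the sources used here. Contigs that share sequence could therefore share reads, and a transcript here is a contig, not a gene. No genome build or coordinates enter the analysis.

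The deposited table holds 1 row for each of 82843 transcripts and 1 value per library, which per the file headers is CPM, the number of reads per 1000000 reads of the library, plus 1. After 1 was subtracted, each column summed to 1000000. The values of each library were then whole multiples of 1 read to within 0.001 reads for 100% of the values above 0. Whole reads per transcript were therefore computed from the deposited CPM. The totals ranged from 38447289 to 50045371 reads, so 1 read was worth 0.020 to 0.026 CPM, and a count of 0 allows a level of up to 0.060 to 0.078 CPM (3 reads). Intervals and floors cover counting error only, because each condition has 1 library. Reads carry no molecular identifiers, so repeated copies of 1 molecule could not be removed. The intervals treat every read as independent and may be too narrow. The deposited ratio column is the authors' ratio of the dark control to the light library on the CPM + 1 scale, and it equals the quotient of the 2 columns. Of the columns with values per sample, 0 were left unused.

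The table pairs its transcript numbers with no gene name, and no reference was used. The 29 pathway and cell type lists fixed before the data were examined could therefore not be applied, and no gene, pathway or cell type is named.

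The 5 planned comparisons set the light library against the dark control, each of the 3 dark-return libraries against the light library, and the 8-day dark-return library against the dark control. Each used log2 of the ratio of (CPM + 1), over the 21307 transcripts with a mean of at least 1 CPM over the 5 libraries. These hold 98.6% to 98.8% of the reads of each library. Because of the added 1 CPM, the ratio understates the difference of low transcripts. A transcript was counted where the ratio was at least 2-fold. For counting error, 100 sets of libraries were simulated in which both libraries share 1 rate per transcript (Poisson reads). The transcripts named are the 2 highest and 2 lowest of each comparison by the ratio of CPM + 1, among those with a mean of at least 5 CPM. The order by the ratio of CPM can differ. For these the ratio of CPM is given with its exact conditional binomial 95% interval (Clopper-Pearson).

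Sets chosen on the light library were followed through the later libraries as the share at least 50% of the way back to the dark control on the log2 scale. For comparison, 100 simulated sets were drawn in which the light library and the 3 later libraries share 1 rate, and the sets were chosen anew in each. Medians were placed among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries and is not a test over animals. A correlation across transcripts was computed between ratios that share no library. Transcripts are not independent replicates, so no p-value is attached.

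The calculation was tested on simulated data for the light library against the dark control, with 21331 transcripts over the filter. Of 100 transcripts changed 3-fold, 83 passed 2-fold, as did 0 of 100 changed 1.5-fold and 0 of 21137 unchanged ones over the filter. The changed transcripts include some that fell under the filter, which count as not passing. Alternatives were pseudocounts of 0.1 and 5 CPM, no filter and means of at least 5 and 10 CPM, thresholds of 1.5- and 4-fold, trimmed-mean-of-M-values (TMM) and median-of-ratios scaling computed on the whole reads, and leaving 1 later library out of the filter. Summing transcripts of the same gene name was not run, because there are no names. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.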

Results

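The series followed the transcriptome of planarians through the loss and return of body pigment. Schmidtea mediterranea is a brown freshwater flatworm whose dorsal pigment is lost under prolonged light and returns when the animals are put back in the dark. The 5 libraries were a dark control of 44297819 reads, an 8-day light library of 38447289 reads, and libraries from light-exposed animals returned to the dark for 1, 2 and 8 days, with 42909193, 50045371 and 48002809 reads. Each library was a pool of 3 biological replicates. At least 1 read was found for 76850 transcripts in the light library and for 78402 in the dark control. The same single transcript was the most abundant in all 5 libraries and took 9.21% to 10.9% of the reads, and the 100 most abundant took 30.0% to 31.2%.

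Light exposure was compared with the dark control to find which transcripts differ when pigment has been lost. Of 21307 transcripts, 356 were at least 2-fold lower in the light library and 137 were at least 2-fold higher, so 72.2% of the 493 differing transcripts were on the lower side. The differences on the lower side were also larger: 58 transcripts were at least 4-fold lower and 16 at least 4-fold higher. On the CPM + 1 scale, by which transcripts are ordered throughout, SmedASXL_002843 was the lowest, at 262 CPM in the dark control and 1.40 CPM in the light library. Its CPM was 186-fold lower, with a 95% counting interval of 143- to 248-fold. SmedASXL_020150 came next, with 77.8 CPM (3446 reads) in the dark control and 1 read in the light library. Its CPM was 2991-fold lower, a ratio that rests on that 1 read, with a counting interval from 536-fold to 118167-fold. By the ratio of CPM it is thus the lower of the pair, as it is with a pseudocount of 0.1 CPM, where the log2 ratios are -9.27 and -7.44.

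On the higher side, the first by the CPM + 1 scale was SmedASXL_013874, at 8.51 CPM in the dark control and 111 CPM in the light library, a 13.0-fold ratio of CPM (interval 11.7 to 14.5). SmedASXL_018815 stood at 22.0 and 188 CPM, an 8.54-fold ratio (7.98 to 9.14). In 100 simulated pairs of libraries without any difference, 0 transcripts reached 2-fold in either direction, so counting error does not produce these numbers; the spread between pools of animals is not known. With a pseudocount of 5 CPM in place of 1 CPM the numbers were 159 lower and 67 higher, and with 0.1 CPM they were 546 lower and 221 higher.

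Among all 10 pairs of libraries, the dark control stood farthest from the rest. It differed at least 2-fold from the light library in 493 transcripts, from the 1-day library in 405, from the 2-day library in 343 and from the 8-day library in 296. Pairs within the other 4 libraries differed in 12 to 146 transcripts. The dark control was at least 2-fold above all 4 other libraries for 136 transcripts and below all 4 for 38. The light library was above the others for 8 transcripts and below them for 7, and the 8-day dark-return library was above for 2 and below for 4. The 2-day library was above for 3 and below for 0, and the 1-day library was above or below the rest for 0. The correlation of log2(CPM + 1) across transcripts was lowest between the dark control and the light library (r = 0.980) and highest between the 1-day and 2-day libraries (r = 0.997).

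**Figure D1:**
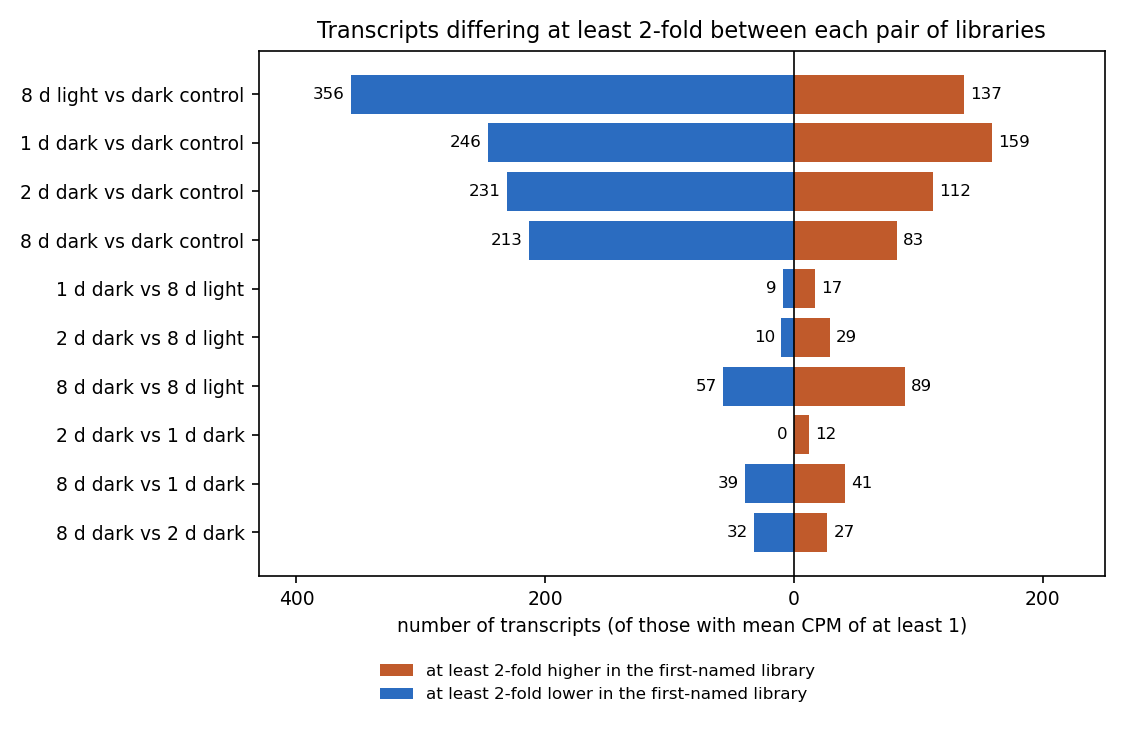
Bars give the number of transcripts, of 21307 with a mean of at least 1 CPM, that were at least 2-fold higher (right) or lower (left) in the first-named library of each pair, with 1 library per condition. The 4 pairs with the dark control have 296 to 493 differing transcripts, and the 6 pairs without it have 12 to 146.

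The libraries from animals returned to the dark were compared with the light library to see what differs as pigment comes back. After 1 day, 17 transcripts were at least 2-fold higher than in the light library and 9 were lower. After 2 days, 29 were higher and 10 were lower. After 8 days, 89 were higher and 57 were lower. Of the transcripts higher at 1 day, 11 were also higher at 2 days and 7 at 8 days, and 18 of the 29 higher at 2 days were higher at 8 days. All 3 sets of ratios share the light library, so part of this overlap may come from that library. Independent lists of these sizes would share 0.023, 0.071 and 0.12, values that leave out the shared library. Simulated libraries without a difference had 0 transcripts past 2-fold and therefore 0 shared, which gives no reference for the overlap.

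At 1 day SmedASXL_023953 stood highest on the CPM + 1 scale, at 0.572 CPM in the light library and 4.24 CPM after 1 day, a 7.41-fold ratio (4.75 to 12.1). SmedASXL_004258 stood at 3.07 and 9.35 CPM, a 3.04-fold ratio (2.47 to 3.77). Their log2 ratios of CPM + 1 were 1.74 and 1.35, and with a pseudocount of 5 CPM both were under 2-fold, at 0.73 and 0.83. The ratio of CPM was larger for SmedASXL_020150, which had 1 read in the light library and 29 reads after 1 day. Lowest at 1 day were SmedASXL_076122, at 16.5 CPM in the light library and 2.28 CPM after 1 day (7.21-fold lower, 5.82 to 9.01), and SmedASXL_064188, at 43.9 and 8.13 CPM (5.39-fold lower, 4.80 to 6.07). These 2 were also the lowest after 2 days, at 2.94 and 8.81 CPM. Both belong to the 8 transcripts in which the light library stood above all others, and those 8 made up all but 1 of the 9 lower transcripts at 1 day and all but 2 of the 10 at 2 days. SmedASXL_023953 was again the highest among transcripts with a mean of at least 5 CPM after 2 days, at 8.03 CPM, a 14.0-fold ratio (9.14 to 22.7). SmedASXL_002439 followed with a 4.08-fold ratio (3.67 to 4.54), at 10.9 CPM in the light library, 24.1 CPM after 1 day, 44.4 CPM after 2 days and 9.31 CPM after 8 days.

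At 8 days SmedASXL_002843 was the highest relative to the light library on the CPM + 1 scale, at 17.0 CPM, a 12.1-fold ratio (9.16 to 16.2). This was still far under its 262 CPM in the dark control. SmedASXL_020150, with 1 read in the light library and 172 reads after 8 days, again had a larger ratio of CPM. Its course was uneven, with 29 reads (0.676 CPM) after 1 day and 4 reads (0.080 CPM) after 2 days. SmedASXL_011484 stood at 187 CPM in the dark control, 58.6 CPM in the light library, 69.5 CPM after 2 days and 300.4 CPM after 8 days, 5.13-fold above the light library on 2253 and 14418 reads. SmedASXL_013874 was the lowest, at 11.5 CPM, 9.62-fold under the light library (8.80 to 10.5) and near its 8.51 CPM in the dark control. SmedASXL_074863 was 9.29-fold lower (7.17 to 12.2), at 12.8 CPM in the light library and 1.37 CPM after 8 days. With a pseudocount of 5 CPM, 1 transcript was higher and 6 were lower after 1 day, 6 and 6 after 2 days, and 31 and 34 after 8 days, so the excess of higher transcripts was not kept at any of the 3 times. It was kept at each time with a mean of at least 10 CPM, with 6 higher and 5 lower, 6 and 4, and 51 and 32.

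Transcripts that differed at the end of light exposure were then followed in the dark. Of the 356 at least 2-fold lower in the light library, 308, 300 and 312 lay above the light library after 1, 2 and 8 days. Their median log2 ratio to the light library was 0.27 after 1 day, 0.29 after 2 days and 0.55 after 8 days. Of the 356, 5.62% were at least 50% of the way back to the dark control after 1 day, 8.99% after 2 days and 27.0% after 8 days, and 17 had reached it by 8 days. The early shares depend on the pseudocount and the filter. With pseudocounts of 0.1 and 5 CPM they were 17.6% and 1.89% after 1 day and 18.5% and 6.29% after 2 days, and with a mean of at least 10 CPM they were 2.45% and 3.68%. Transcripts at least 2-fold higher in the light library mirrored this course, with median log2 ratios of -0.24, -0.26 and -0.49, and 37.2% of the 137 were at least 50% of the way back after 8 days.

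The sets were chosen on the light library, which also enters the later ratios. In simulated libraries with no change after light exposure, the mean of the median at 8 days was 0.0077 for the lower set and -0.0055 for the higher set, and at most 0.427% of the lower set came 50% of the way back by 8 days. These simulated libraries hold counting error only, so they cannot show what variation between pools in the light library would add. Random lists matched on expression had medians between -0.0025 and 0.091 at 8 days for the lower set. When the set was chosen instead on the 1-day library against the dark control, so that neither the light nor the 8-day library entered the choice, its 246 lower transcripts had a median log2 ratio of 0.55 between the 8-day and light libraries, with 198 of them higher at 8 days. The 159 higher transcripts had a median of -0.27. The share 50% of the way back was not examined under this choice.

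**Figure D2:**
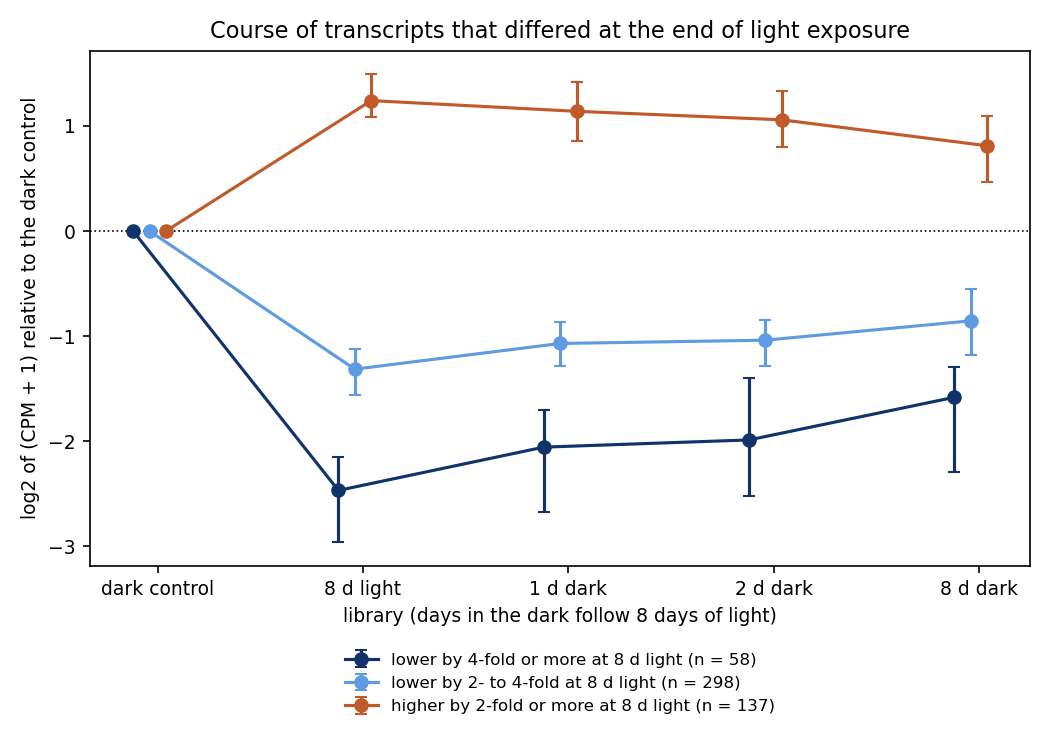
Points give the median log2 of (CPM + 1) relative to the dark control in each of the 5 libraries, and bars the quartiles over transcripts, for the sets chosen on the light library. The 58 transcripts lower by 4-fold or more had a median of -1.58 after 8 days in the dark, the 298 lower by 2- to 4-fold a median of -0.85, and the 137 higher ones a median of 0.81.

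The lower transcripts were also divided by the size of their difference in the light library. The 58 lower by 4-fold or more had median log2 ratios to the light library of 0.43, 0.54 and 0.87 after 1, 2 and 8 days, and the 298 lower by 2- to 4-fold had 0.24, 0.27 and 0.50. As a share of the way back the order differed between times. Of the 58, 5.17%, 17.2% and 12.1% were at least 50% of the way back after 1, 2 and 8 days, against 5.70%, 7.38% and 29.9% of the 298. Of the 10 among the 58 that were 50% of the way back after 2 days, 6 were transcripts at least 2-fold higher after 2 days than after 1 day, whose reads kept 1 ratio over the 5 libraries within counting noise. Without these 6, the number was 4 after 2 days and 7 after 8 days. Levels that were higher at each step from the light library through 1, 2 and 8 days were seen for 116 of the 356 lower transcripts (32.6%), against 8.65% of all transcripts and a highest share of 8.90% in the simulated sets. Levels that were lower at each step were seen for 48 of the 137 higher transcripts (35.0%), against 6.19% of all transcripts. The light library is the first step and also chose both sets, and the simulated sets hold counting error only. Variation between pools in the light library would also raise these shares, so neither reference is matched to them. The shares were not computed for sets chosen on another library.

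The series' design text mentions 75 genes of interest with a high ratio of control to depigmented animals. The 75 transcripts with the highest ratio and a mean of at least 1 CPM were therefore described here; 72 of them are among the first 75 of the authors' deposited table, which is sorted by that ratio. They were chosen on these libraries, so their direction in the light library is no independent evidence. The same choice may raise their later levels relative to the light library, and no reference for that was computed for the 75. Their ratios ran from 3.73- to 109-fold. The median level was 9.30 CPM in the dark control, 0.832 CPM in the light library, and 1.65, 2.34 and 2.85 CPM after 1, 2 and 8 days in the dark. As a share of each transcript's own control level, the median was 9.09% in the light library, 24.1% after 2 days and 28.3% after 8 days. After 8 days 74 of the 75 were above the light library, 27 by at least 2-fold. The number still at least 2-fold under the dark control was 72 after 1 day, 62 after 2 days and 67 after 8 days, and the number 50% of the way back was 4, 12 and 10. Without the same 6 transcripts, these were 66, 62 and 61 under the control and 4, 6 and 10 at 50% of the way back. The 6 were found by their rise between 1 and 2 days, so the others among the 75 may still include contigs that share reads.

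The 8-day dark-return library was compared with the dark control to see what still differs. It held 213 transcripts at least 2-fold lower and 83 at least 2-fold higher. Of the 356 transcripts lower in the light library, 167 were among the 213, and of the 137 higher ones, 49 were among the 83. These comparisons share the dark control. Independent lists would share 3.56 and 0.534, values that leave out the shared control, so part of the excess may come from it. Simulated libraries without a difference again had 0 transcripts in either list and give no reference. On the CPM + 1 scale SmedASXL_020150 was the lowest, at 3.58 CPM, 21.7-fold under the control (18.6 to 25.5), followed by SmedASXL_012615 at 86.0 CPM in the control and 4.73 CPM after 8 days (18.2-fold lower, 15.9 to 20.9). Highest were SmedASXL_006173, at 1.54 and 20.5 CPM (13.4-fold, 10.4 to 17.3), and SmedASXL_019323, at 2.30 and 27.0 CPM (11.7-fold, 9.58 to 14.5). Both were above the control in all 4 other libraries. The first stood at 3.36, 4.57 and 7.69 CPM in the light library and after 1 and 2 days, and the second at 5.64, 6.11 and 14.2 CPM. At a threshold of 1.5-fold the split of this comparison was even, with 576 lower and 571 higher.

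Across transcripts, the difference between the dark control and the light library was compared with later movement in the dark, with no library in both ratios. The log2 ratio of control to light correlated with that of the 8-day to the 1-day library at r = 0.291 (Spearman rho = 0.194) and with that of the 8-day to the 2-day library at r = 0.328 (rho = 0.283). After shuffling, the highest of 100 values was 0.018 and 0.016. Shuffling treats transcripts as independent, which they are not, so these values give no reference for differences between pools that many transcripts share. Without the 493 transcripts that differed 2-fold, r was 0.223 and 0.294. Of those 493, 355 differed between the 8-day and 1-day libraries in the direction of the control (72.0%), and 344 between the 8-day and 2-day libraries (69.8%).

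**Figure D3:**
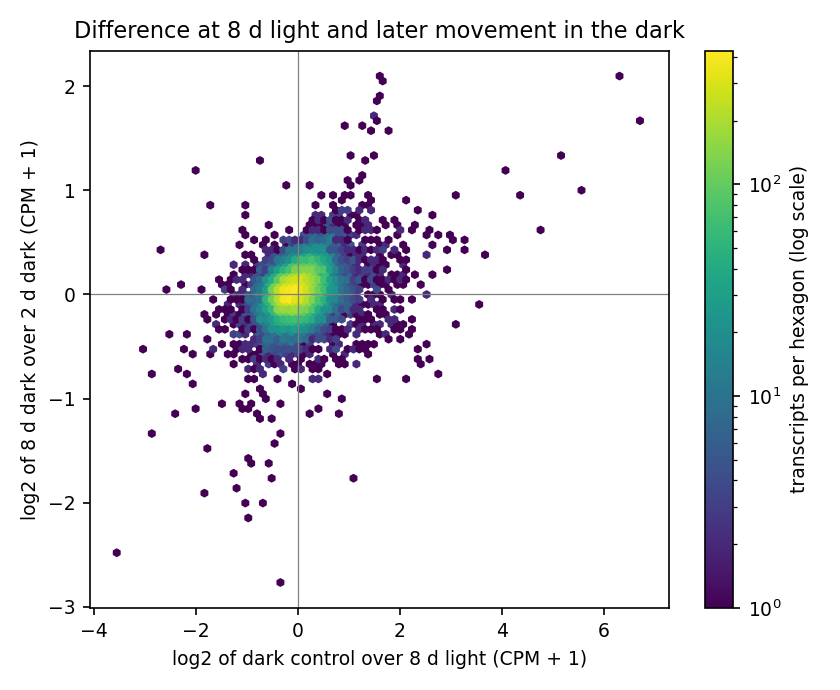
Each hexagon holds transcripts placed by the log2 ratio of the dark control to the light library (x axis) and of the 8-day to the 2-day dark-return library (y axis), both of CPM + 1, with color for the number of transcripts on a log scale. The cloud of 21307 transcripts tilts upward (r = 0.328).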

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

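The tests of time without food, of counting error for the 8 transcripts and of 1 source for the 6 transcripts were chosen after the values behind them had been seen. The thinning and the removal of abundant transcripts were chosen after the table had been examined, before their results.

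SmedASXL_002439 is listed because its direction differed between time points: its log2 ratio to the light library was 1.08 after 1 day and 1.93 after 2 days in the dark, and -0.21 after 8 days. The 95% counting intervals of its ratio of CPM were 1.97 to 2.48, 3.67 to 4.54 and 0.746 to 0.979. The last excludes 1 by little, for a transcript picked out of 14 for its change of direction, so a level under the light library at 8 days is not established. The difference between time points was not tested across animals.

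The dark control stood at least 2-fold apart from all 4 other libraries for 174 transcripts, against 15 or fewer for each of the others. The scaling and a few abundant transcripts are argued against, since the number was 175 with TMM scaling and 200 without the 100 most abundant transcripts. That removal scales up the CPM of the rest against the same pseudocount, which can itself raise the number. With every library thinned to the smallest total the number was 169. Thinning could hardly have lowered it, because the control's total of 44297819 reads lies between those of the other libraries. The thinning therefore gives no evidence on depth. Suppose that animals went unfed through the whole course and that the effect of time without food only grows. As the whole cause, time without food would then place the 8-day dark-return library at least as far from the control as the light library. The light library differed in 493 transcripts and the 8-day library in 296, which argues against that cause only under these assumptions. Neither assumption was tested. For the 216 transcripts that differed the same way in the light and 8-day libraries, time without food, an effect of light that lasts, and another difference of the control pool cannot be told apart, because the control is 1 library and the only one without light. The labels give 1 week without food for all animals and do not give feeding during the course.

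The light library was at least 2-fold above all 4 others for 8 transcripts, whose medians were 7.35 CPM in the dark control, 30.2 CPM in the light library and 5.69 CPM after 1 day in the dark. SmedASXL_012104, named after its values were seen, went from 3375 CPM in the control to 9005 CPM in the light library and 2160 CPM after 1 day. Counting error is argued against by a highest number of 0 such transcripts in 100 simulated sets. A single source for all reads of the 8 is argued against too. Their reads did not keep 1 ratio over the 5 libraries (chi-square of 43.9 per degree of freedom). The ratio of the light to the 1-day library ran from 2.65 to 7.21. Contigs that share only part of their reads would also vary in ratio, and some of the 8 could share reads without the rest. Such sharing stays open. A short-lived response to light and a peculiarity of that 1 pool both stay open and were not tested.

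For 6 transcripts, at least 4-fold lower in the light library than in the control and at least 2-fold higher after 2 days than after 1 day in the dark, the medians were 8.70, 0.806, 1.55, 4.91 and 2.85 CPM in the order control, light, 1, 2 and 8 days. Their reads kept 1 ratio over the 5 libraries within counting noise (chi-square of 0.785 per degree of freedom), which is consistent with contigs of 1 transcript or contigs that share reads. If so, they may be 1 event rather than 6 among the 29 transcripts higher at 2 days and the 12 higher at 2 days than at 1 day. No biological explanation was tested for them, and contig sequences were not used here. Apart from these 6 and the 8 transcripts above, no other set of contigs was examined for 1 ratio.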

How the results depend on the processing

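No paired analysis was possible because each condition had 1 library. Thinning, leaving out the 100 most abundant, the 8 light-library or the 6 2-day transcripts, counting consecutive contig numbers once and choosing the set on another library were added after the data were seen, and the others were planned. Results for gene lists and for sums per gene name were not run, because there are no names. The direction of every followed median, correlation and named transcript held under all alternatives run. For a single named transcript, a pseudocount or a filter cannot change the direction. Only the scalings could have, and they shifted libraries little, so the direction of named transcripts was barely tested. The size moved, and for comparisons with the light library so did the balance of higher and lower transcripts: the excess of higher ones after 1, 2 and 8 days was lost or turned with a pseudocount of 5 CPM, and turned after 1 and 2 days at 4-fold, while stricter filters kept it. A larger pseudocount compresses the ratios of low transcripts, and a stricter filter leaves fewer transcripts to count. Leaving out the 100 most abundant transcripts scales up the CPM of the rest against the same pseudocount and filter, which can itself raise the numbers. For the other moves the cause was not tested.

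In the order light against control, then 1, 2 and 8 days against light, then 8 days against control, a pseudocount of 0.1 CPM gave 221, 83, 88, 200 and 160 higher transcripts and 546, 14, 15, 87 and 288 lower ones. A pseudocount of 5 CPM gave 67, 1, 6, 31 and 46 higher and 159, 6, 6, 34 and 105 lower. A mean of at least 5 CPM gave 107, 10, 11, 67 and 73 higher and 211, 7, 7, 42 and 125 lower, and one of at least 10 CPM gave 86, 6, 6, 51 and 60 higher and 163, 5, 4, 32 and 100 lower. At 1.5-fold the numbers were 744, 153, 128, 425 and 571 higher and 1138, 27, 36, 229 and 576 lower, and at 4-fold 16, 0, 2, 9 and 6 higher and 58, 3, 3, 6 and 25 lower. Without the 100 most abundant transcripts, 32 and 45 were higher after 1 and 2 days. Without the 8 transcripts above all others in the light library, 1 and 2 were lower after 1 and 2 days. Scaling by TMM or median of ratios, no filter, thinning to the smallest library and counting runs of consecutive contig numbers once kept all 10 numbers within 1.5-fold. Neither scaling moved the split of higher and lower by 10 points.

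The dark control was above all others for 68 transcripts with a pseudocount of 5 CPM, 81 with a mean of at least 5 CPM and 68 with at least 10 CPM. It was below all others for 76 and 20 with pseudocounts of 0.1 and 5 CPM.

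For the lower set, the share 50% of the way back after 1 day was 17.6% and 1.89% with pseudocounts of 0.1 and 5 CPM, and 2.84% and 2.45% with means of at least 5 and 10 CPM. After 2 days it was 18.5%, 6.29%, 4.27% and 3.68%, and after 8 days it was 38.8% with 0.1 CPM. For the higher set it was 4.65% after 2 days with a mean of at least 10 CPM. The lower set's median log2 ratio to the light library with pseudocounts of 0.1 and 5 CPM was 0.34 and 0.16 after 1 day, 0.38 and 0.22 after 2 days, and 0.62 and 0.44 after 8 days. It was 0.21 after 1 day with median-of-ratios scaling, and 0.49 after 8 days without a filter. The higher set's was -0.28 after 1 day with TMM and -0.31 with median of ratios. After 8 days it was -0.27 and -0.21 when the set was chosen on the 1-day or 2-day library against the control. Leaving a later library out of the filter gave 5.54% to 5.56%, 8.86% to 9.14% and 26.9% for the lower set's share after 1, 2 and 8 days, and 0.55 for its median after 8 days.

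The correlation with the 8-day to 1-day ratio was 0.334 with a pseudocount of 5 CPM, 0.213 without a filter, and 0.365 and 0.390 with means of at least 5 and 10 CPM. That with the 8-day to 2-day ratio was 0.304 and 0.370 with pseudocounts of 0.1 and 5 CPM, 0.231 without a filter, and 0.405 and 0.425 with the higher means. For the 75 transcripts, the median log2 ratio of the 8-day library to the control, -1.50 as first computed, was -1.81 and -1.10 with pseudocounts of 0.1 and 5 CPM and -1.19 and -1.16 with means of at least 5 and 10 CPM. Depth limits little above the filter, where 1 CPM is 38.4 to 50.0 reads. The spread between pools is not known at any depth.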

Other observations

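The class limits and the test in this part were chosen after the data were seen. The 89 transcripts at least 2-fold higher after 8 days in the dark than in the light library were classed by how much of that difference was present after 2 days. For 29 of them, under 25% of the log2 difference was present after 2 days, for 34 at least 50% was, and 26 lay between. The place of each class at 2 days, the late one near the light library and the early one far from it, follows from how the classes were chosen, and no reference for the sizes of the classes was computed. The 8-day library also chose the 89, so a peculiarity of that 1 pool would place transcripts in the late class and raise their level at 8 days. Late timing and such a peculiarity cannot be told apart here. The 29 late transcripts had a median log2 ratio to the dark control of -1.27 in the light library and 0.14 after 8 days. By 8 days 26 of them were within 2-fold of the control and 19 were above it. The 34 early transcripts had a lower median in the light library, -1.88, and stood at -1.05, -0.77 and -0.45 after 1, 2 and 8 days, with 12 still at least 2-fold under the control. Of these 34, 5 belong to the 6 transcripts whose reads kept 1 ratio over the libraries, and without them the medians were -1.72, -0.89, -0.81 and -0.37. SmedASXL_011484 belongs to the late class.

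Among the 57 transcripts at least 2-fold lower after 8 days than in the light library, 26 were late, 13 lay between and 18 were early. The late ones had a median log2 ratio of 0.70 in the light library and -0.75 after 8 days, and by then 7 of the 26 were at least 2-fold under the control. Of the 18 early ones, 8 are the transcripts in which the light library stood above all others, for which a peculiarity of that pool stays open. The way these 8 were chosen places them among the 57 and favors the early class, without fixing it. The other 10 had a median of 2.07 in the light library, 1.46 after 1 day, 1.26 after 2 days and 0.66 after 8 days. The 8-day library chose the 57 as well, so a peculiarity of that pool cannot be told apart from late timing in their late class either. The intervals between libraries are uneven, so the timing between days 2 and 8 is not resolved.

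A hypothesis was that contigs with consecutive assembly numbers come from 1 gene or from related genes, so that numbers of transcripts overstate numbers of genes. Over 14017 consecutive pairs the log2 ratio of light to control correlated at r = 0.0994, above the highest of 100 shuffles (0.020) but just under the 0.1 set as needed. Of these pairs, 28 differed at least 2-fold the same way on both sides, against a mean of 4.79 and a highest of 13 in the shuffles. The correlation is thus small and missed the level set, while the number of such pairs exceeded every shuffle. Counting such runs once left 10 of 10 numbers within 1.5-fold. That count covers only contigs with consecutive numbers, and the 6 transcripts whose reads kept 1 ratio do not have consecutive numbers. Whether numbers of transcripts overstate numbers of genes is therefore not settled.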
